A study of Rattus norvegicus with 36 samples.

How the data were processed

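Gene expression was measured in 36 rat kidneys, 1 array per animal, from 70 mg of tissue and 500 ng of RNA each. All animals were males 8 weeks old, and the kidneys were taken on day 14. The values deposited by the authors are signals in the unit intensity, on a linear scale, made with MAS5 per the submitters' processing notes. The version of MAS5 is not given in the sources used here. The deposited intensity values are scaled per array: the mean after trimming 2% of the values was 99.993 in every array. No 2 arrays had identical columns (0 found).

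Probe sets were named from the gene table supplied for the array, with symbols updated through Entrez identifiers to the RefSeq gene table of the GRCr8 assembly, from which no coordinates were used. Of the 31099 probe sets, 20832 had 1 symbol, 436 had several and 9831 had none, and 20764 of those with 1 symbol matched a current entry. Probe sets with several symbols or none were tested but not named.

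The signals were offset by 5.35, their 20th percentile over all values, and log2 transformed. The 57 control probe sets were left out, as were probe sets whose mean signal was not above 16.9, the 40th percentile, in at least 1 of the 7 groups. This left 20024 probe sets, of which 14940 were named, standing for 11074 genes, and 5084 were not. Signals near that background level limit what could be detected for weakly expressed genes.

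A linear model with 1 mean per group was fitted to all 36 arrays in limma 3.58.1 under R 4.3.3, with moderated tests that follow the intensity trend (eBayes). It had 29 residual degrees of freedom and a median of 5.32 prior degrees of freedom. Tests were two-sided, and p values were adjusted by Benjamini and Hochberg over the 20024 probe sets within each comparison, with a threshold of 0.05. The 9 comparisons were each serum dose against the controls of its strain, WKY controls against SD controls, the strain difference of the response to 5 ml/kg, and the highest against the lowest serum dose in each strain. Values are log2 fold changes with the standard error (SE) of the model, and signals are group means with the standard deviation (SD) between animals.

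Groups, comparisons, offset, filter, thresholds, gene lists, the rule for named genes and the alternatives listed below were set before the data were examined. By that rule, the 8 named genes with the highest and the 8 with the lowest log2 fold change among those past the threshold were named for WKY at 5 ml/kg, SD at 5 ml/kg, the controls and the strain difference, with 1 probe set per gene, that of the highest mean. In serum comparisons the 4 tested members of a list with the largest change at 5 ml/kg in each strain were added, whether or not they passed; the text gives values for part of them. Havcr1, Lcn2, Nphs1, Col1a1 and Cd68 were named in every serum comparison. 1 further gene of this fixed set is not reported here.

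Of 30 gene lists with 494 members, 369 members were tested, 61 were below the filter and 64 had no probe set with their single symbol. The neutrophil, mast cell, red blood cell and adrenal lists had fewer than 3 tested members and were not tested, which left 26. A shift of a list against all other genes was tested with camera in limma, with a preset correlation of 0.01 between genes and again with the correlation estimated from the residuals, and p values were adjusted over the lists of a comparison. Lists share members: Egf is in the injury and distal tubule lists, C1q genes are in the macrophage and complement lists, and Spp1, Timp1 and Cxcl10 are also in more than 1.

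Recovery was tested only on simulated data (20024 probe sets), at 1.5-fold, 2-fold and 4-fold. It was 73.1%, 91.0% and 98.5% for WKY and 91.0%, 97.0% and 100% for SD at 5 ml/kg. It was 70.1%, 94.0% and 100% for WKY at 1 ml/kg, 76.1%, 97.0% and 98.5% for the controls and 46.3%, 83.6% and 97.0% for the strain difference. Each had 7 to 13 unchanged probe sets called, and real rates may differ.

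The alternatives were quantile normalization, median centring, no offset with a floor at the 5th percentile, an offset at the 40th percentile, no filter, a filter at the 60th percentile, no intensity trend, robust eBayes, only the groups compared, array quality weights, at least 1.5-fold as well, shared-sequence probe sets left out, 1 probe set per gene, the replicate number as a block, and each array left out in turn. For lists they also included the mean over all probe sets of a gene. Covariates for the 3'/5' ratios of Actb and Gapdh were chosen after seeing the data. Figures and tables used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.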

Results

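RNA from the kidneys of 36 male rats was measured on Affymetrix rat genome arrays, 14 days after a single intravenous dose of nephrotoxic serum or saline. Nephrotoxic serum here is sheep antiserum against rat glomerular basement membrane, and it causes an immune injury of the glomerulus. Sprague-Dawley (SD) rats, an outbred stock, received saline (6 animals), 1.5 ml/kg (6 animals) or 5 ml/kg of serum (6 animals). Wistar-Kyoto (WKY) rats, an inbred strain known for severe glomerulonephritis after this serum, received saline (3 animals), 1 ml/kg (5 animals), 2.5 ml/kg (5 animals) or 5 ml/kg (5 animals). The dose groups ask how the kidney transcriptome changes with serum dose within each strain, and the pairing of strains asks whether the response differs between them.

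The deposited table held signals for 31099 probe sets in each of the 36 arrays. Median signals ran from 27.7 to 32.1 between arrays. The correlation of log2 signals between any pair of arrays was between 0.964 and 0.992. After ± and beside n, SD stands for the standard deviation. The number of arrays per group limits the precision of each value, most of all for the 3 WKY controls. Principal component 1 held 33.5% of the variance and component 2 held 22.5%, and SD arrays had lower values on component 1 than WKY arrays of the same treatment.

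**Figure D1:**
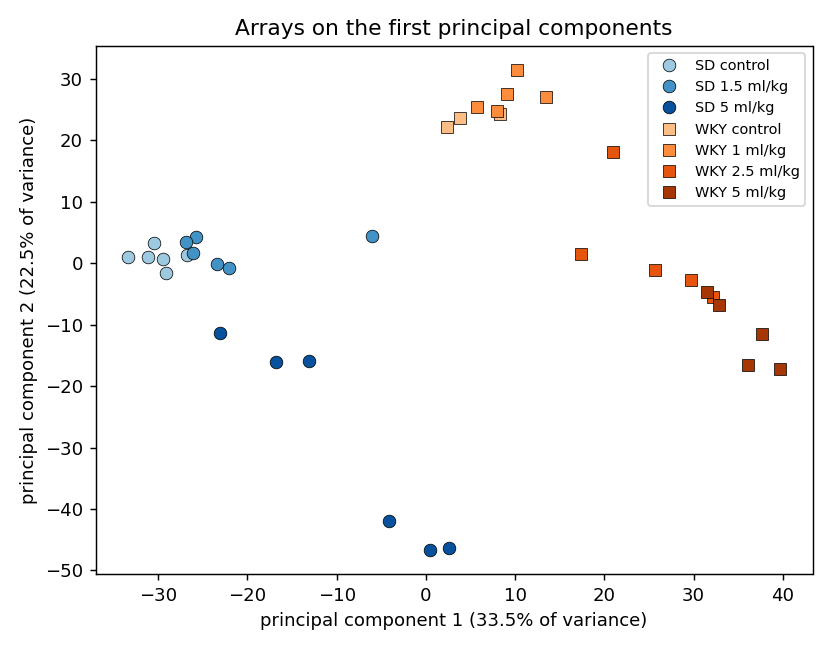
Each point is 1 of the 36 arrays on principal component 1 (horizontal axis, 33.5% of variance) and principal component 2 (vertical axis, 22.5% of variance) of the log2 signals, with circles for SD, squares for WKY and darker colours for higher serum doses in ml/kg. Along component 1 the 6 SD controls lie between -33.3 and -26.8 and the 5 WKY animals given 5 ml/kg between 31.5 and 39.7.

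The comparison of WKY rats given 5 ml/kg with WKY controls asks what the highest dose did in the susceptible strain. Havcr1, which encodes the tubular injury marker KIM-1, had the largest rise, 5.34 on the log2 scale (SE 0.469, adjusted p = 3.28e-09). Its signal was 18.4 ± 6.06 in controls (SD, n = 3, range 11.4 to 22.0) and 948 ± 166 after serum (SD, n = 5, range 670 to 1116). The acute-phase protease inhibitor A2m rose by 3.27 (SE 0.506, adjusted p = 2.43e-05). The injury marker Lcn2, which encodes NGAL, rose by 3.02 (SE 0.463, adjusted p = 2.16e-05). Complement factor I (Cfi) rose by 2.79 (SE 0.391, adjusted p = 8.2e-06). Ltbp2, a latent TGF-β binding protein of the matrix, rose by 2.75 (SE 0.396, adjusted p = 1.1e-05). The other genes among the 8 largest rises were the α1D-adrenergic receptor Adra1d at 2.35 (SE 0.405, adjusted p = 7.86e-05), the β-tubulin Tubb6 at 2.28 (SE 0.284, adjusted p = 2.02e-06) and the oxidised LDL receptor Olr1 at 2.27 (SE 0.376, adjusted p = 5.35e-05). Control signals of A2m, Cfi, Ltbp2, Adra1d and Olr1 lay below the filter value of 16.9, so the offset limits these rises and their order. Over all alternatives Ltbp2 ran from 1.85 to 3.83, Adra1d from 1.61 to 3.13 and Olr1 from 1.62 to 2.86.

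The deepest fall among named genes was in Klk1c4, of the kallikrein family, at -2.58 (SE 0.645, adjusted p = 0.00347). Cyp2c11, a male-specific cytochrome P450 of the rat, followed at -2.50 (SE 0.793, adjusted p = 0.0185), and the amino acid transporter Slc7a12 at -2.35 (SE 0.415, adjusted p = 0.000103). Gc, the vitamin D-binding protein, changed by -2.24 (SE 0.386, adjusted p = 7.84e-05). Urah, an enzyme of urate breakdown, changed by -1.96 (adjusted p = 7.14e-05), from signals of 178 ± 23.9 (SD, n = 3) to 43.7 ± 17.7 (SD, n = 5). Mlana, which encodes melan-A, was called lower, but its signal after serum lay below the filter value of 16.9. Its change ran from -2.75 to -1.05 over all alternatives. The nuclease Dnase1 changed by -1.68 (adjusted p = 1.56e-05) and the carnosinase Cndp1 by -1.66 (adjusted p = 2.56e-05). Without WKY control 1, 2 or 3, the adjusted p of Cyp2c11 was 0.0512, 0.0519 or 0.0619.

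In limma, 5129 of 20024 probe sets passed an adjusted p of 0.05 in WKY at 5 ml/kg, 2852 higher and 2277 lower. They stood for 2086 named genes higher and 1551 lower, and 269 probe sets rose and 100 fell at least 2-fold. A further requirement of 1.5-fold left 1523 probe sets, and array quality weights gave 7887.

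**Figure D2:**
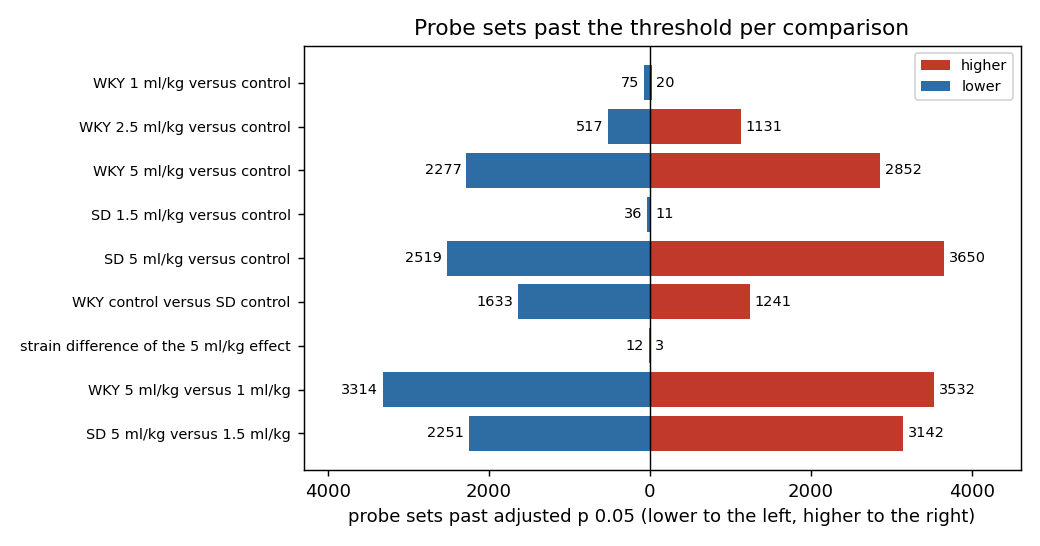
Bars give the number of probe sets past an adjusted p of 0.05 in each of the 9 comparisons, with higher ones to the right in red and lower ones to the left in blue, on a linear axis from 0. WKY at 5 ml/kg had 2852 higher and 2277 lower, and SD at 5 ml/kg had 3650 higher and 2519 lower.

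Among gene lists fixed in advance, injury genes of the tubule had the highest median in WKY at 5 ml/kg, although camera gave lower p values to the macrophage, proliferation and matrix lists. Of the 23 tested members, 20 rose and 1 fell, and adjusted over the list alone 20 rose and 2 fell. After Havcr1 and Lcn2 the largest rises were in Gpnmb, a glycoprotein of lysosomes, at 2.26 (SE 0.292, adjusted p = 3.13e-06), and in the secreted chaperone Clu at 2.22 (SE 0.271, adjusted p = 1.5e-06). The list's median was 1.07 and it shifted upward in camera (adjusted p = 9.33e-12, and adjusted p = 0.077 with an estimated correlation). Egf, a growth factor of the distal tubule that is lost in injury, was the member that fell, by 0.40.

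Macrophage genes rose in 17 of 18 members, adjusted over the list alone also 17, with a median of 0.97 (camera adjusted p = 2.27e-12, and adjusted p = 0.0968 with an estimated correlation). Mrc1, the mannose receptor of macrophages, rose by 1.81 (SE 0.317, adjusted p = 9.21e-05), the inhibitory Fc receptor gene Fcgr2b by 1.66 (SE 0.231, adjusted p = 7.58e-06) and the lysosomal marker Cd68 by 1.17 (SE 0.198, adjusted p = 6.72e-05). Cd68 signals were 52.2 ± 4.81 in controls (SD, n = 3, range 46.6 to 55.0) and 124 ± 11.3 after serum (SD, n = 5, range 108 to 135). The C1q genes, shared by the macrophage and complement lists, rose as well, C1qa by 1.32 (adjusted p = 0.000331) and C1qb by 1.29 (adjusted p = 0.00012). Fcgr3a, the low-affinity Fc receptor, was the member not past the threshold, at 0.11.

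The complement list rose in 9 of 13 members (adjusted over the list alone 9 rose and 1 fell), led by Cfi, with a median of 0.66 (camera adjusted p = 7.02e-05, and adjusted p = 0.146 with an estimated correlation). MHC class II genes, which present antigen, rose in 9 of 11, also adjusted over the list alone, with a median of 0.76 (camera adjusted p = 2.39e-05, and adjusted p = 0.0968 with an estimated correlation). RT1-Db1 rose by 1.12 (SE 0.162, adjusted p = 1.12e-05) and RT1-Da by 1.06 (SE 0.155, adjusted p = 1.28e-05). Chemokines and cytokines rose in 12 of 20 (12 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 7.02e-05, and adjusted p = 0.077 with an estimated correlation). Their largest changes were in the lymphoid chemokine Ccl21 at 1.33 (SE 0.215, adjusted p = 4.25e-05), osteopontin (Spp1) at 1.28 (SE 0.154, adjusted p = 1.38e-06), the monocyte chemokine Ccl2 at 1.27 (SE 0.226, adjusted p = 0.00011) and the B-cell chemokine Cxcl13 at 0.92 (adjusted p = 0.00726).

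Interferon-responsive genes rose in 11 of 22 (11 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.00131, and adjusted p = 0.339 with an estimated correlation). Psmb8 and Psmb9, subunits of the immunoproteasome, rose by 1.44 (adjusted p = 2.88e-06) and 0.94 (adjusted p = 3.44e-05), the transcription factor Irf1 by 0.89 (adjusted p = 5.49e-06) and the chemokine Cxcl10 by 0.80 (adjusted p = 4.88e-05). The antiviral genes Mx1 at 0.14, Irf7 at 0.01 and Isg15 at 0.01 were not past the threshold. All 3 tested B-cell and plasma-cell genes rose, also adjusted over the list alone, with Jchain, the joining chain of polymeric antibodies, at 2.01 (SE 0.321, adjusted p = 3.56e-05) and a list median of 0.64 (camera adjusted p = 0.0209, and adjusted p = 0.0859 with an estimated correlation). T-cell and NK-cell genes rose in 2 of 11 (2 adjusted over the list alone), the T-cell kinase Lck at 0.62 (adjusted p = 0.000262) and the receptor chain Cd3g at 0.74 (adjusted p = 0.011), and the list was not past the threshold (median 0.17, camera adjusted p = 0.209).

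Matrix and fibrosis genes rose in 24 of 31 members, adjusted over the list alone also 24, with a median of 0.87 (camera adjusted p = 2.99e-12, and adjusted p = 0.0968 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose by 2.16 (SE 0.307, adjusted p = 9.63e-06), and the collagen cross-linking enzymes Loxl1 by 1.54 (SE 0.219, adjusted p = 9.32e-06) and Lox by 1.50 (SE 0.210, adjusted p = 8.2e-06). Collagen I (Col1a1) rose by 1.23 (SE 0.195, adjusted p = 3.35e-05), from signals of 152 ± 19.985 (SD, n = 3) to 365 ± 53.5 (SD, n = 5). Mesangial, pericyte and smooth muscle genes rose in 8 of 12 (11 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.000132, and adjusted p = 0.0968 with an estimated correlation). Among them were the contractile protein gene Tagln at 1.07 (adjusted p = 0.000371), the adhesion molecule Mcam at 0.79 (adjusted p = 0.000152), the protease inhibitor Serpine2 at 0.72 (adjusted p = 0.00358) and the receptor Pdgfrb at 0.67 (adjusted p = 0.000319). The other tested probe sets of Mcam (1) and Pdgfrb (2) were not called higher.

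Proliferation genes rose in 24 of 27 (26 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 2.27e-12, and adjusted p = 0.0859 with an estimated correlation). Cdk1, the kinase of mitotic entry, rose by 1.08 (SE 0.162, adjusted p = 1.58e-05), the proliferation marker Mki67 by 1.08 (SE 0.157, adjusted p = 1.19e-05) and the cyclin Ccnb2 by 0.97 (adjusted p = 2.29e-05). Immediate early genes rose in 6 of 9 (6 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.00039, and adjusted p = 0.146 with an estimated correlation). Among them Fos was at 1.84 (SE 0.303, adjusted p = 4.98e-05), Egr1 at 1.48 (adjusted p = 0.000637), Atf3 at 1.34 (adjusted p = 1.16e-05) and Jun at 0.83 (adjusted p = 0.0011). Targets of p53 rose in 4 of 9 (4 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.0163, and adjusted p = 0.0859 with an estimated correlation). These were Phlda3 at 1.02 (adjusted p = 2.3e-05), the death receptor Fas at 0.73 (adjusted p = 0.000252), the cell-cycle inhibitor Cdkn1a at 0.69 (adjusted p = 0.000132) and Bbc3 at 0.39 (adjusted p = 0.00163).

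Nephrin (Nphs1), the slit diaphragm protein of podocytes, fell by 0.47 (SE 0.144, adjusted p = 0.0152), from 138 ± 7.90 (SD, n = 3, range 133 to 148) to 98.7 ± 7.25 (SD, n = 5, range 91.0 to 111). The podocyte list did not move as 1 group: 3 of 13 members rose and 2 fell, also adjusted over the list alone, with a median of -0.03 (camera adjusted p = 0.733). The transcription factors Dach1 and Tcf21 moved apart, at -0.44 (SE 0.0924, adjusted p = 0.000626) and 0.60 (adjusted p = 0.000566). The endothelial list gave 1 gene higher and 1 lower of 14, also adjusted over the list alone, with a median of 0.01, a mean of -0.03 and no shift (camera adjusted p = 0.793). Vwf, the clotting factor of endothelial cells, fell by 0.75 (adjusted p = 0.00445), while the growth factor receptor Flt1 was at -0.37 (adjusted p = 0.208) and the co-receptor Eng at 0.29 (adjusted p = 0.0744). Without WKY control 2, the adjusted p of Nphs1 was 0.0687, and Eng had an adjusted p of 0.0028 in a fit of only the groups compared and 0.00994 with array weights.

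Collecting duct genes fell in 6 of 12 (8 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 2.39e-05, and adjusted p = 0.146 with an estimated correlation). They included the anion exchangers Slc4a1 at -0.87 (SE 0.182, adjusted p = 0.00067) and Slc26a4 at -0.72 (adjusted p = 0.00512) and the proton pump subunit Atp6v1b1 at -0.76 (SE 0.138, adjusted p = 0.000134). Loop and distal tubule genes fell in 4 of 8, also adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.0104, and adjusted p = 0.329 with an estimated correlation). Among them the potassium channel Kcnj1 was at -0.73 (adjusted p = 0.00353) and the calcium receptor Casr at -0.50 (adjusted p = 0.00898). Proximal tubule genes fell in 8 of 24 and rose in 3 (8 and 4 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.0514). The organic ion transporters Slc22a2 and Slc22a7 fell, by 1.03 (adjusted p = 0.000753) and 0.72 (adjusted p = 0.00103), while the sulfate transporter Slc13a1 rose by 0.95 (adjusted p = 6.55e-05) and the glucose transporter Slc2a2 by 0.71 (adjusted p = 0.0026). The proximal tubule list had adjusted p values of 0.0168 without WKY control 1, 0.037 without WKY control 2, 0.0294 and 0.0295 without animals 2 and 5 of the 5 ml/kg group, and 0.0123 with quantile normalization.

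Cholesterol synthesis genes fell in 6 of 10 (7 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 1.12e-05, and adjusted p = 0.077 with an estimated correlation): the reductase Dhcr7 was at -0.82 (adjusted p = 5.94e-06), the sterol sensor Insig1 at -0.68 (adjusted p = 2.25e-05), the isomerase Idi1 at -0.64 (adjusted p = 2.25e-05) and the demethylase Cyp51 at -0.64 (adjusted p = 0.000148). Fatty acid oxidation genes fell in 7 of 16, also adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.0051, and adjusted p = 0.253 with an estimated correlation). Its enzymes Ehhadh at -0.47 (adjusted p = 0.00518), Acadm at -0.39 (adjusted p = 0.00479) and Echs1 at -0.38 (adjusted p = 0.00191) were among them. Oxidative phosphorylation and citric acid cycle genes fell in 3 of 17, also adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.00602, and adjusted p = 0.407 with an estimated correlation). These were the dehydrogenase Mdh2 at -0.25 (adjusted p = 0.00129) and the complex I subunits Ndufs1 at -0.23 (adjusted p = 0.00359) and Ndufa9 at -0.22 (adjusted p = 0.00225).

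Oxidative stress genes fell in 6 of 16 and rose in 1 (7 and 2 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.0237, and adjusted p = 0.339 with an estimated correlation). The glutathione transferase Gstp1 fell by 0.57 (adjusted p = 0.00108), and without WKY control 3 the list had an adjusted p of 0.0841. The transferrin receptor gene Tfrc, held in the housekeeping list, fell by 1.12 (SE 0.163, adjusted p = 1.21e-05), and the ribosomal gene Rplp0 rose by 0.27 (adjusted p = 0.000392). That list gave 3 higher and 1 lower of 8, also adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.209). In the renin-angiotensin list 1 of 8 genes fell, also adjusted over the list alone, the mineralocorticoid receptor Nr3c2 at -0.53 (adjusted p = 0.00393), with a median of -0.08 (camera adjusted p = 0.209). The adipose list, which marks fat around the kidney, had 1 of 5 lower, also adjusted over the list alone, the lipid droplet gene Cidec at -1.10 (adjusted p = 6.84e-05), with a median of -0.27 (camera adjusted p = 0.128, and 0.0382 without WKY control 3). None of 4 urothelium genes was called in limma, also adjusted over the list alone (median -0.09, camera adjusted p = 0.748).

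Some calls in WKY at 5 ml/kg were lost without 1 animal. The fold held or shrank: without WKY control 1, Egf was -0.42 and Cd3g 0.52. Without WKY control 1, adjusted p values were 0.0927 for the class II gene RT1-Ba (1.17 with every array), 0.132 for Cd3g (0.74), 0.0605 for the B-cell factor Pou2af1 (0.64), 0.119 for the B-cell gene Fcrla (0.54), 0.0968 for heme oxygenase Hmox1 (0.57), 0.0754 for the lysosomal enzyme Gusb (0.38) and 0.0528 for the ribosomal gene Rpl13a (0.22). They were 0.0625 for the protease Plat (0.26), 0.0579 for Etfdh of fatty acid oxidation (-0.39), 0.0779 for Egf (-0.40), 0.0604 for the glutathione enzyme Gclm (-0.40) and 0.105 for the water channel Aqp4 (-0.64). Without WKY control 2, they were 0.0595 for RT1-Ba, 0.125 for the podocyte filament gene Nes (0.36), 0.07 for Plat, 0.0566 for the salt transporter Slc12a3 (-0.40), 0.0901 for Egf and 0.11 for Aqp4. Without WKY control 3, they were 0.18 for the mitotic kinase Plk1 (1.04), 0.108 for Pou2af1, 0.0687 for Fcrla, 0.0588 for Nes, 0.0944 for Plat, 0.0585 for catalase Cat (-0.35), 0.0615 for Etfdh, 0.0674 for Slc12a3, 0.121 for Egf and 0.0726 for Gclm. Without animal 1 of the 5 ml/kg group they were 0.0898 for Egf and 0.0661 for Aqp4, without animal 2 0.0586 for Pou2af1 and 0.0758 for Fcrla, and without animal 3 0.0756 for Nes and 0.0758 for Plat. Without animal 4 they were 0.0953 for Egf and 0.0616 for Plat, and without animal 5 0.059 for Fcrla, 0.0537 for Egf and 0.06 for Aqp4. The replicate block gave 0.0523 for RT1-Ba, 0.0505 for Plat and 0.058 for Egf, no filter 0.0601 for Egf, and quantile normalization 0.0579 for Nes. RT1-Bb was at 1.11 with an SE of 1.01 (adjusted p = 0.449), and a fit of only the groups compared gave an adjusted p of 3.55e-06.

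**Figure D3:**
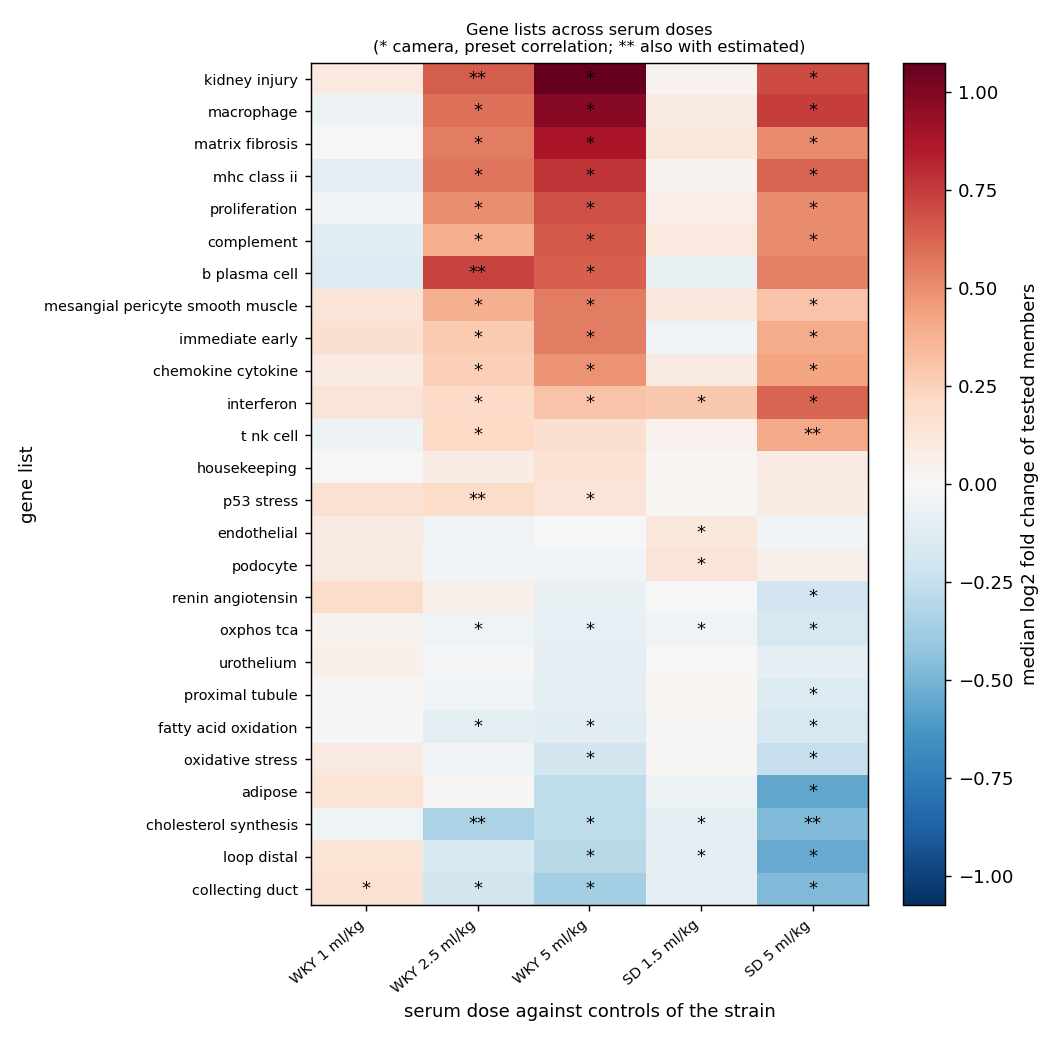
Colour gives the median log2 fold change of the tested members of each gene list (vertical axis) for each serum dose against the controls of its strain (horizontal axis). The injury list stood at 1.07 in WKY and 0.70 in SD at 5 ml/kg, where 1 star marks a camera adjusted p under 0.05 with the preset correlation and a pair of stars one that also holds with an estimated correlation.

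At the middle dose of 2.5 ml/kg in WKY, injury genes rose again. Havcr1 rose by 4.33 (SE 0.469, adjusted p = 7.91e-07) to a signal of 496 ± 172 (SD, n = 5, range 193 to 594), and Lcn2 by 2.28 (SE 0.463, adjusted p = 0.00336). Ltbp2 rose by 2.22 (adjusted p = 0.00121), A2m by 2.16 (adjusted p = 0.00905), Cfi by 1.89 (adjusted p = 0.0039) and Clu by 1.67 (adjusted p = 0.000505). Spp1 rose by 1.22 (SE 0.154, adjusted p = 1.26e-05), Timp1 by 1.51 (adjusted p = 0.00336) and Fcgr2b by 1.27 (adjusted p = 0.00142). Urah changed by -1.29 (adjusted p = 0.0168), Dnase1 by -1.05 (adjusted p = 0.0104), Tfrc by -1.04 (adjusted p = 0.000323) and Cndp1 by -0.92 (adjusted p = 0.0237). Nphs1 stood at -0.29 (SE 0.144, adjusted p = 0.211), with an adjusted p of 0.0267 under array weights.

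Col1a1 rose by 0.76 at 2.5 ml/kg (SE 0.195, adjusted p = 0.0153), but its adjusted p was 0.0881 without WKY control 1 and 0.0599 without WKY control 3. Cd68 rose by 0.70 (SE 0.198, adjusted p = 0.0242), with signals of 89.7 ± 18.6 (SD, n = 5) against 52.2 ± 4.81 (SD, n = 3). Its adjusted p was 0.115, 0.0647 or 0.0715 without WKY control 1, 2 or 3, 0.0665 or 0.0507 without animal 1 or 4 of the dose group, and 0.0535 with the replicate number as a block.

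In limma, 1648 probe sets passed in WKY at 2.5 ml/kg, 1131 higher and 517 lower, and median centring of the arrays gave 558 higher and 1411 lower. At least 2-fold changes were higher in 93 and lower in 10. The count was 565, 651 or 506 without WKY control 1, 2 or 3, 1057 or 869 without animal 1 or 4 of the dose group, 4276 with array weights and 487 with at least 1.5-fold.

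Of the 26 lists, 13 shifted upward and 4 downward at 2.5 ml/kg, and 4 of these held with an estimated correlation. Injury genes rose in 15 of 23 (17 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 2.79e-12, and adjusted p = 0.0381 with an estimated correlation). Cholesterol synthesis genes fell in 5 of 10 (8 adjusted over the list alone), at a median of -0.34 (camera adjusted p = 6.78e-09, and adjusted p = 0.0177 with an estimated correlation). The B-cell and plasma-cell list rose in 2 of 3 (3 adjusted over the list alone, median 0.72, camera adjusted p = 0.0052, and adjusted p = 0.0381 with an estimated correlation). The p53 list rose in 4 of 9 (5 adjusted over the list alone, median 0.20, camera adjusted p = 0.0063, and adjusted p = 0.0381 with an estimated correlation). Macrophage genes rose in 14 of 18 (16 adjusted over the list alone), at a median of 0.59 (camera adjusted p = 9.61e-10, and adjusted p = 0.158 with an estimated correlation). Matrix genes rose in 16 of 31 (23 adjusted over the list alone), at a median of 0.55 (camera adjusted p = 7.65e-10, and adjusted p = 0.158 with an estimated correlation). Proliferation genes rose in 15 of 27 (23 adjusted over the list alone), at a median of 0.50 (camera adjusted p = 9.52e-12, and adjusted p = 0.102 with an estimated correlation).

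In WKY rats given 1 ml/kg, none of the injury genes named at higher doses was past the threshold. Havcr1 was at 0.31 (SE 0.469, adjusted p = 0.875), with signals of 24.3 ± 8.13 (SD, n = 5), Lcn2 at 0.03 (adjusted p = 0.99), Nphs1 at 0.21 (adjusted p = 0.648), Col1a1 at 0.12 (adjusted p = 0.89) and Cd68 at 0.04 (adjusted p = 0.971). The sodium-coupled proximal tubule transporters Slc5a12 at -1.02 (adjusted p = 0.00245) and Slc4a4 at -0.65 (adjusted p = 0.00673) fell. Igfbp3, a binding protein of insulin-like growth factors, fell by 1.31 (SE 0.208, adjusted p = 0.00214) and the metalloprotease gene Adamts8 rose by 0.93 (SE 0.139, adjusted p = 0.00189). Igfbp3, Adamts8, Slc5a12 and Slc4a4 were chosen after their values were seen.

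In limma, 95 probe sets passed at 1 ml/kg in WKY, 20 higher and 75 lower, and 2171 had an unadjusted p under 0.05. The 3'/5' signal ratio of the control transcript Gapdh, which rises as RNA degrades, was 1.44 ± 0.104 in this group (SD, n = 5) and 1.30 ± 0.0449 in WKY controls (SD, n = 3), and that of Actb was 5.74 ± 0.521 and 4.95 ± 0.297. With the Gapdh ratio as a covariate, chosen after seeing the data, 2 probe sets passed, and with the Actb ratio 39. The count was 51, 26 or 0 without WKY control 1, 2 or 3, and 50, 54 or 37 without animal 1, 4 or 5 of the dose group. It was 51 with no filter, 353 with only the groups compared, 543 with array weights, 50 with the replicate block and 47 with at least 1.5-fold.

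The collecting duct list shifted upward at 1 ml/kg, with 0 of 12 members called in limma, also adjusted over the list alone, and a median of 0.16 (camera adjusted p = 0.0254, and adjusted p = 0.818 with an estimated correlation). Its adjusted p was 0.089 without WKY control 3 and 0.0528, 0.0712 or 0.0738 without animal 1, 2 or 5 of the dose group. In the proximal tubule list 3 of 24 members fell (adjusted over the list alone 6 fell and 3 rose), with a median of 0.01, a mean of -0.12 and a downward test (camera adjusted p = 0.147). Quantile normalization gave that list an adjusted p of 0.000129, and leaving out WKY control 1 gave 0.0486. Leaving out WKY control 1 gave the proliferation list an adjusted p of 0.0486 and leaving out WKY control 2 gave the endothelial list 0.0397. The injury list had 0 of 23 members called (1 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.272).

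SD rats given 5 ml/kg had Havcr1 as the largest rise as well, at 5.15 (SE 0.371, adjusted p = 1.2e-11). Its signal was 17.8 ± 5.29 in SD controls (SD, n = 6, range 11.2 to 25.6) and 1050.2 ± 664 after serum (SD, n = 6, range 140 to 1830). Lcn2 rose by 2.92 (SE 0.366, adjusted p = 9.17e-07), with signals after serum from 39.9 to 721 (n = 6), and A2m by 2.72 (SE 0.400, adjusted p = 7.99e-06). The cytokine Il24 rose by 2.21 (SE 0.226, adjusted p = 3.82e-08), Cfi by 2.20 (SE 0.309, adjusted p = 4.37e-06), the fibrillar collagen Col24a1 by 2.15 (SE 0.210, adjusted p = 1.34e-08), the glutathione peroxidase Gpx2 by 2.13 (SE 0.239, adjusted p = 1.62e-07) and Ltbp2 by 2.11 (SE 0.313, adjusted p = 8.74e-06). Control signals of A2m, Il24, Cfi, Col24a1 and Ltbp2 lay below 16.9. Over all alternatives Il24 ran from 1.46 to 3.12, Col24a1 from 1.42 to 3.03 and Ltbp2 from 1.32 to 3.35. Rbp4, the retinol-binding protein, had the deepest fall at -2.30 (SE 0.359, adjusted p = 1.68e-05), from 219.9 ± 81.6 (SD, n = 6) to 46.2 ± 40.7 (SD, n = 6). The desaturase Scd changed by -1.88 (SE 0.552, adjusted p = 0.00934), the protocadherin Pcdh9 by -1.54 (adjusted p = 0.00565), Slc7a12 by -1.39 (adjusted p = 0.00153) and Gc by -1.34 (adjusted p = 0.00108). The chloride channel gene Ano2 was called lower as well, but its signals lay below the filter value of 16.9 in both groups.

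Calls in SD at 5 ml/kg for Cyp2c11, Klk1c4, Nphs1 and Col1a1 were less stable. Cyp2c11 was at -1.77 (SE 0.627, adjusted p = 0.0296), with adjusted p values of 0.0754, 0.0812 or 0.104 without SD control 3, 4 or 6, of 0.0653, 0.1 or 0.0808 without animal 2, 4 or 5 of the dose group, and of 0.123 with only the groups compared. Klk1c4 was at -1.49 (SE 0.510, adjusted p = 0.0247), with 0.0551 or 0.0732 without SD control 3 or 5, 0.0963 or 0.0774 without animal 4 or 5 of the dose group, and 0.0819 with only the groups compared. Nphs1 was at -0.31 (SE 0.114, adjusted p = 0.0373), with signals of 149 ± 10.7 (SD, n = 6) and 123 ± 36.3 (SD, n = 6, range 83.1 to 161). Its adjusted p was 0.0614, 0.0744 or 0.0695 without SD control 1, 3 or 6, 0.148, 0.105 or 0.13 without animal 2, 4 or 5 of the dose group, 0.0532 with no filter, 0.165 with only the groups compared and 0.0601 with array weights. Col1a1 was at 0.49 (SE 0.154, adjusted p = 0.0145), with 0.0662 or 0.0536 without animal 2 or 4 of the dose group and 0.0733 with only the groups compared. Cd68 rose by 0.95 (SE 0.157, adjusted p = 3.36e-05), from 51.4 ± 4.199 (SD, n = 6) to 111 ± 43.5 (SD, n = 6, range 67.6 to 155).

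**Figure D4:**
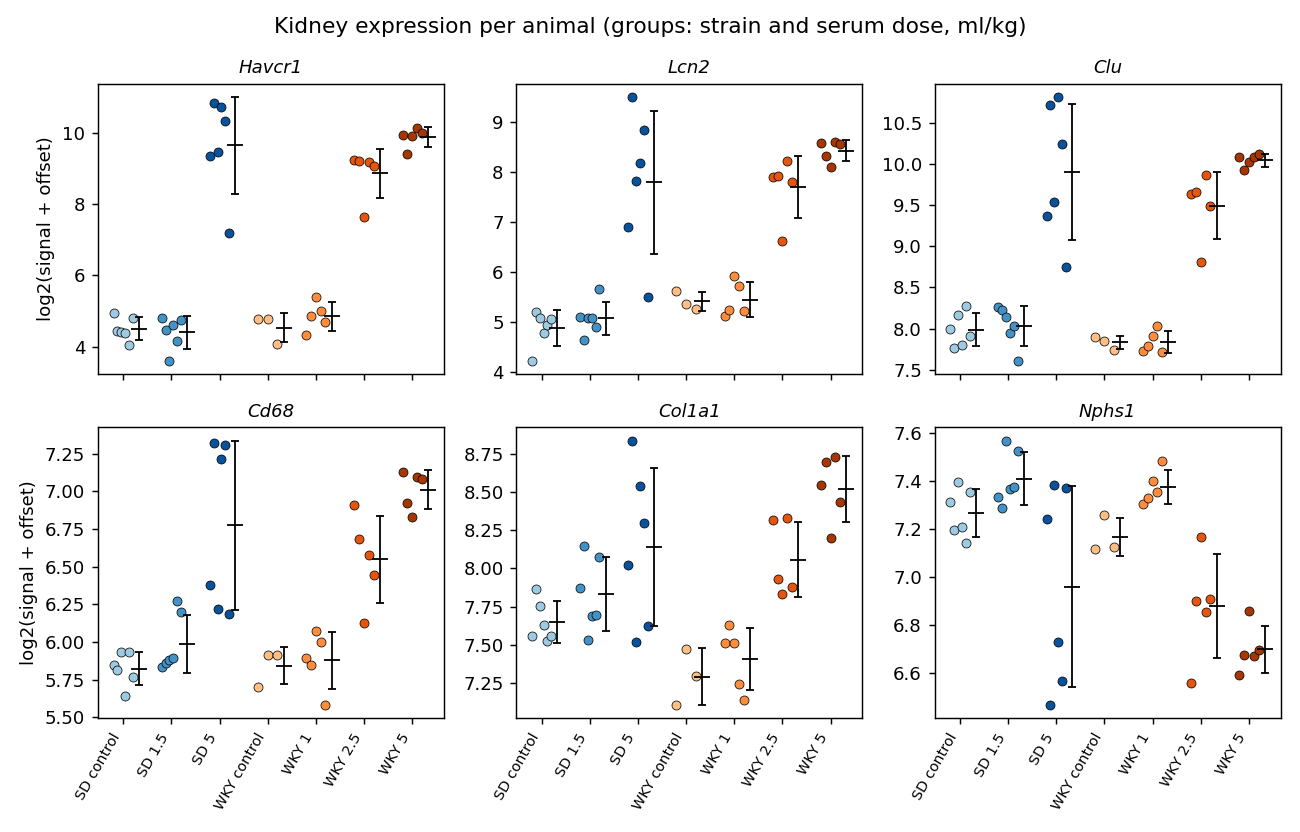
Each point is 1 animal, with log2 of signal plus offset on the vertical axis and the 7 groups (strain and serum dose in ml/kg) on the horizontal axis, and black bars give the mean and SD of the group. Havcr1 signals lay between 670 and 1116 in WKY at 5 ml/kg and between 140 and 1830 in SD at 5 ml/kg.

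The 6 SD animals given 5 ml/kg lay in separate sets on principal component 2, animals 2, 4 and 5 between -46.7 and -41.98 and animals 1, 3 and 6 between -16.1 and -11.3. SD controls lay between -1.62 and 3.24. Cd68 signals were 143 to 155 in the first set and 67.6 to 78.0 in the other. Nphs1 signals were 83.1 to 101 and 146 to 161. Values for this group, and strain differences that use it, average over these unequal animals.

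In limma, 6169 probe sets passed in SD at 5 ml/kg, 3650 higher and 2519 lower. Median centring gave 2136 higher and 4147 lower. At least 2-fold changes were higher in 143 and lower in 43.

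Injury genes rose in 18 of 23 and fell in 2 in SD at 5 ml/kg (19 and 2 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 9.84e-09, and adjusted p = 0.111 with an estimated correlation). The members that fell were Egf, at -0.54, and the trefoil factor Tff3, at -0.56, while Clu rose by 1.92 (adjusted p = 1.56e-07) and Gpnmb by 1.84 (adjusted p = 9.17e-07). Macrophage genes rose in 18 of 18, also adjusted over the list alone, with a median of 0.75 (camera adjusted p = 1.65e-09, and adjusted p = 0.125 with an estimated correlation). Among them were C1qa at 1.13 (adjusted p = 0.000103) and Fcgr2b at 1.09 (adjusted p = 3.93e-05). T-cell and NK-cell genes rose in 9 of 11 (11 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.000319, and adjusted p = 0.0308 with an estimated correlation). Cd3g rose by 0.93 (SE 0.170, adjusted p = 0.000101), Lck by 0.78 (SE 0.0950, adjusted p = 5.09e-07) and the kinase Zap70 by 0.52 (adjusted p = 0.000591). Interferon-responsive genes rose in 17 of 22 (19 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 9.84e-09, and adjusted p = 0.125 with an estimated correlation). Ifit1 rose by 1.06 (adjusted p = 0.00632), Psmb8 by 0.98 (adjusted p = 8.53e-06), Irf1 by 0.93 (adjusted p = 3.9e-08) and the peptide transporter Tap1 by 0.88 (adjusted p = 2.33e-06).

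Complement genes rose in 9 of 13 in SD (10 adjusted over the list alone, median 0.51, camera adjusted p = 2.71e-05, and adjusted p = 0.125 with an estimated correlation). MHC class II genes rose in 7 of 11, also adjusted over the list alone (median 0.62, camera adjusted p = 0.000249, and adjusted p = 0.125 with an estimated correlation). Chemokines and cytokines rose in 11 of 20 (13 adjusted over the list alone, median 0.42, camera adjusted p = 0.000217, and adjusted p = 0.111 with an estimated correlation). B-cell and plasma-cell genes rose in 2 of 3 (3 adjusted over the list alone, median 0.54, camera adjusted p = 0.101). Matrix genes rose in 23 of 31 (adjusted over the list alone 25 rose and 1 fell), with a median of 0.50 (camera adjusted p = 1.13e-07, and adjusted p = 0.142 with an estimated correlation). Mesangial, pericyte and smooth muscle genes rose in 7 of 12, also adjusted over the list alone (median 0.31, camera adjusted p = 0.00504, and adjusted p = 0.142 with an estimated correlation).

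Proliferation genes rose in 22 of 27 in SD (adjusted over the list alone 24 rose and 1 fell), with a median of 0.51 (camera adjusted p = 3.15e-07, and adjusted p = 0.138 with an estimated correlation). Plk1 was at 1.15 (adjusted p = 0.00106) and the replication factor Mcm3 at 0.85 (adjusted p = 2.9e-06). Immediate early genes rose in 4 of 9 (5 adjusted over the list alone, median 0.40, camera adjusted p = 0.00903, and adjusted p = 0.215 with an estimated correlation). The p53 list rose in 4 of 9, also adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.0565). That list had adjusted p values of 0.0446 with quantile normalization, 0.0401 or 0.04 without SD control 2 or 5, and 0.0426, 0.0462 or 0.0485 without animal 2, 4 or 5 of the dose group. The podocyte list gave 2 higher and 1 lower of 13, also adjusted over the list alone (median 0.06, camera adjusted p = 0.543). Nes was at 0.54 (adjusted p = 6.78e-05). The endothelial list gave 2 higher and 2 lower of 14, also adjusted over the list alone (median -0.03, camera adjusted p = 0.464).

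Cholesterol synthesis genes fell in 8 of 10 in SD (9 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 3.82e-09, and adjusted p = 0.0119 with an estimated correlation). Idi1 was at -0.94 (SE 0.0782, adjusted p = 5.07e-10), Insig1 at -0.89 (adjusted p = 5.08e-09), Cyp51 at -0.78 (adjusted p = 3.08e-07) and the epoxidase Sqle at -0.63 (adjusted p = 2.92e-05). Oxidative phosphorylation genes fell in 13 of 17 (15 adjusted over the list alone, median -0.17, camera adjusted p = 1.57e-07, and adjusted p = 0.125 with an estimated correlation). Fatty acid oxidation genes fell in 10 of 16, also adjusted over the list alone (median -0.17, camera adjusted p = 0.00013, and adjusted p = 0.125 with an estimated correlation). Collecting duct genes fell in 8 of 12, also adjusted over the list alone (median -0.47, camera adjusted p = 1.03e-05, and adjusted p = 0.125 with an estimated correlation). Loop and distal tubule genes fell in 7 of 8, also adjusted over the list alone (median -0.54, camera adjusted p = 1.85e-05, and adjusted p = 0.125 with an estimated correlation). Proximal tubule genes fell in 10 of 24 and rose in 4 (12 and 5 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.0161, adjusted p = 0.356 with an estimated correlation, and 0.153 with quantile normalization).

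Oxidative stress genes fell in 8 of 16 and rose in 1 in SD (9 and 3 adjusted over the list alone, median -0.25, camera adjusted p = 0.000502, and adjusted p = 0.125 with an estimated correlation). Renin-angiotensin genes fell in 5 of 8, also adjusted over the list alone (median -0.20, camera adjusted p = 0.00244, and adjusted p = 0.125 with an estimated correlation). Adipose genes fell in 3 of 5, also adjusted over the list alone (median -0.56, camera adjusted p = 0.0169, and adjusted p = 0.204 with an estimated correlation). The housekeeping list gave 3 higher and 1 lower of 8, also adjusted over the list alone, with a median of 0.09, a mean of -0.05 and no shift (camera adjusted p = 0.601), and Tfrc at -1.25 (SE 0.129, adjusted p = 3.95e-08).

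SD rats given 1.5 ml/kg showed no call among the injury genes named above: Havcr1 was at -0.10 (SE 0.371, adjusted p = 0.957), Lcn2 at 0.20 (adjusted p = 0.912), Nphs1 at 0.14 (adjusted p = 0.714), Col1a1 at 0.19 (adjusted p = 0.725) and Cd68 at 0.17 (adjusted p = 0.78). Bcl6, a transcriptional repressor of lymphocytes, rose by 1.31 (adjusted p = 0.0402), from 261 ± 79.2 (SD, n = 6) to 654 ± 166 (SD, n = 6), and the steroid enzyme Hsd17b1 by 1.34 (adjusted p = 0.0402). The clock gene Nr1d1 rose by 0.93 (SE 0.172, adjusted p = 0.013), and Pdxdc1, a decarboxylase-like gene, changed by -1.01 (SE 0.160, adjusted p = 0.00698). Nr1d1 and Pdxdc1 were chosen after their values were seen. In limma, 47 probe sets passed, 11 higher and 36 lower, and 2235 had an unadjusted p under 0.05. Median centring gave 28 higher and 28 lower.

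The count in SD at 1.5 ml/kg was 16, 20, 21 or 10 without SD control 1, 2, 3 or 4, and 25, 21 or 23 without animal 2, 5 or 6 of the dose group. It was 0 with only the groups compared, 10 with 1 probe set per gene, 18 with the Actb ratio as a covariate (chosen after seeing the data) and between 25 and 31 with no filter, a stricter filter, no offset, no trend or at least 1.5-fold, and an offset at the 40th percentile gave 82.

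The interferon list shifted most at 1.5 ml/kg in SD, with 0 of 22 members called in limma (16 adjusted over the list alone) and a median of 0.29 (camera adjusted p = 1.26e-14, and adjusted p = 0.0739 with an estimated correlation). Ifit1 was at 0.89, Irf7 at 0.53 and Mx1 at 0.47, none past the threshold over all probe sets. Podocyte genes had 0 of 13 called (5 adjusted over the list alone, median 0.14, camera adjusted p = 0.000142, and adjusted p = 0.124 with an estimated correlation). Endothelial genes had 0 of 14 called (3 adjusted over the list alone, median 0.11, camera adjusted p = 0.00503, and adjusted p = 0.0739 with an estimated correlation). Cholesterol synthesis genes had 0 of 10 called (4 lower adjusted over the list alone, median -0.09, camera adjusted p = 1.25e-05, and adjusted p = 0.0739 with an estimated correlation).

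The loop and distal tubule list (median -0.10) and the oxidative phosphorylation list (median -0.04) also passed at 1.5 ml/kg in SD, both at a camera adjusted p of 0.0187. With an estimated correlation they had 0.885 and 0.938. In limma 0 of 8 and 0 of 17 members were called, and 1 and 0 adjusted over the list alone. Each list lost its call without SD control 4 or 6 or animal 5 or 6 of the dose group (adjusted p 0.0517 to 0.118). So did the loop list with quantile normalization (0.0569), and the other with the mean over probe sets (0.106) and without SD control 5 (0.0624).

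Comparisons between doses within a strain set no control animals against treated ones, but the controls, as part of the model, help to set the residual spread. From 1 to 5 ml/kg in WKY, Havcr1 rose by 5.03 (SE 0.406, adjusted p = 6.48e-10), Cfi by 3.20 (SE 0.338, adjusted p = 3.36e-08), Lcn2 by 2.99 (adjusted p = 9.25e-07), Cd68 by 1.13 (SE 0.171, adjusted p = 4.93e-06) and Col1a1 by 1.11 (SE 0.169, adjusted p = 5.06e-06). Nphs1 changed by -0.68 (SE 0.124, adjusted p = 7.34e-05) and Slc7a12 by -2.67 (adjusted p = 9.75e-07). In limma, 6846 probe sets passed, 3532 higher and 3314 lower, and 4508 passed with 1 probe set per gene and 1672 with at least 1.5-fold. Collecting duct genes fell in 12 of 12, also adjusted over the list alone, with a median of -0.51 (camera adjusted p = 7.25e-08, and adjusted p = 0.0918 with an estimated correlation). Macrophage genes rose in 17 of 18 (18 adjusted over the list alone, median 1.08, camera adjusted p = 3.73e-13, and adjusted p = 0.0918 with an estimated correlation) and proliferation genes in 26 of 27, also adjusted over the list alone (median 0.74, camera adjusted p = 3.73e-13, and adjusted p = 0.0918 with an estimated correlation). Proximal tubule genes went both ways, 13 lower and 7 higher of 24 (14 and 8 adjusted over the list alone), with a median of -0.19, a mean of 0.04 and a downward test (camera adjusted p = 0.291). The 3'/5' ratio of Gapdh was 1.44 ± 0.104 at 1 ml/kg (SD, n = 5) and 1.32 ± 0.0480 at 5 ml/kg (SD, n = 5).

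From 1.5 to 5 ml/kg in SD, Havcr1 rose by 5.25 (SE 0.371, adjusted p = 1.34e-11), Lcn2 by 2.72 (SE 0.366, adjusted p = 5.15e-06) and Cd68 by 0.78 (SE 0.157, adjusted p = 0.000429). Nphs1 changed by -0.45 (SE 0.114, adjusted p = 0.00355) and Rbp4 by -2.35 (SE 0.359, adjusted p = 2.59e-05), while Col1a1 was at 0.30 (adjusted p = 0.141). In limma, 5393 probe sets passed, 3142 higher and 2251 lower. Median centring gave 1417 higher and 4883 lower, quantile normalization 2434 higher and 2726 lower. A fit of only the groups compared gave 2553 and at least 1.5-fold 840. T-cell and NK-cell genes rose in 8 of 11 (9 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.000344, and adjusted p = 0.0439 with an estimated correlation). Cholesterol synthesis genes fell in 7 of 10, also adjusted over the list alone, with a median of -0.36 (camera adjusted p = 1.8e-06, and adjusted p = 0.0439 with an estimated correlation).

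The comparison of saline controls asks how the strains differ before injury. RT1-T24-4, a class I gene of the major histocompatibility complex, was lower in WKY, at -4.05 (SE 0.139, adjusted p = 1.83e-21), with signals of 588 ± 112 in SD (SD, n = 6) and 29.99 ± 1.53 in WKY (SD, n = 3). The integrin Itga1 was at -3.10 (SE 0.384, adjusted p = 6e-07), LOC100910237 at -2.55 (adjusted p = 9.67e-13), the pyrophosphatase Enpp1 at -2.44 (SE 0.0968, adjusted p = 6.57e-20), the tubular basement membrane antigen Tinag at -2.43 (adjusted p = 3.03e-13), the peroxisomal gene Pxmp4 at -2.21 (adjusted p = 9.67e-13) and the leukocyte integrin Itgal at -2.17 (adjusted p = 6.1e-13). The synaptic vesicle gene Sv2b was at -2.24 (adjusted p = 0.00435), and at an adjusted p of 0.0595 without WKY control 2. Higher in WKY were Spetex2l2 at 2.97 (SE 0.171, adjusted p = 6.39e-15), Urah at 1.94 (adjusted p = 5.55e-05), the phospholipase Plaat1 at 1.83 (adjusted p = 5.33e-05), Hsd17b1 at 1.81 (adjusted p = 0.000482), the centromere gene Mis18a at 1.80 (adjusted p = 6.9e-06) and the class I gene RT1-CE5 at 1.70 (SE 0.127, adjusted p = 5.26e-12). Signals of LOC100910237 and Itgal in WKY, and of Spetex2l2 and Plaat1 in SD, lay below the filter value of 16.9, so the offset limits these differences. RT1-Bb, a class II gene, was at 4.68 (SE 0.974, adjusted p = 0.000833), but another of its probe sets was at -4.59 (adjusted p = 1.5e-05). Of 151 genes with at least 2-fold strain differences at 1 probe set and another probe set to compare, 42 (27.8%) had the change followed by the other.

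Cyp2c11 was higher in WKY controls at 2.26 (SE 0.768, adjusted p = 0.043), with SD control signals from 30.2 to 579 (n = 6). Its adjusted p was 0.1, 0.0816 or 0.0973 without SD control 1, 2 or 5 and 0.107, 0.121 or 0.122 without WKY control 1, 2 or 3. It was 0.063 with no filter, 0.0551 with no offset, 0.052 with no trend, 0.0662 with robust eBayes, 0.0777 with only the groups compared, 0.0528 with 1 probe set per gene, and 0.0577 and 0.0508 with the Actb and Gapdh ratios as covariates, chosen after seeing the data.

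In limma, 2874 probe sets differed between the controls, 1241 higher and 1633 lower in WKY. Median centring gave 1863 higher and 1362 lower. At least 2-fold differences were higher in 66 and lower in 297. The count was 1639 without WKY control 2, 4517 with array weights, 1191 with 1 probe set per gene and 1096 with at least 1.5-fold. Cholesterol synthesis genes were lower in 5 of 10 (adjusted over the list alone 6 lower and 1 higher), with a median of -0.25 (camera adjusted p = 0.000279, and adjusted p = 0.259 with an estimated correlation). Matrix genes were lower in 6 of 31 (8 adjusted over the list alone), with a median of -0.07 and a mean of -0.20 (camera adjusted p = 0.0191, adjusted p = 0.92 with an estimated correlation, and 0.149 with the mean over probe sets). The proliferation list had an adjusted p of 0.0371 without WKY control 2, and the oxidative phosphorylation list 0.0253 without SD control 1 and 0.0107 without WKY control 3.

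The difference between strains in the response to 5 ml/kg was tested as an interaction. Itgal, the αL chain of the leukocyte integrin LFA-1, was called, but its signals in WKY were 13.0 ± 3.64 in controls (SD, n = 3) and 7.20 ± 2.31 after serum (SD, n = 5). Both lie below the filter value of 16.9, so its response in WKY and the strain difference cannot be read from this probe set. In SD its signals were 76.4 ± 7.92 (SD, n = 6) and 126 ± 21.5 (SD, n = 6). For Bcl6 the WKY response minus the SD response was -2.22 (SE 0.463, adjusted p = 0.0448), with -1.22 in WKY and 1.00 in SD. Nid1, a basement membrane linker, was at 0.61 (SE 0.121, adjusted p = 0.0372), with 0.51 in WKY and -0.09 in SD. The secretory stress factor Xbp1 was at -0.34 (adjusted p = 0.0372), the ciliary gene Bbs7 at -0.64 (adjusted p = 0.036), the membrane gene Palm3 at -0.76 (adjusted p = 0.0372) and the epidermal transcription factor Znf750 at -0.91 (adjusted p = 0.0398). Injury markers did not pass: Havcr1 differed by 0.19 (SE 0.598, adjusted p = 0.928), Lcn2 by 0.10 (adjusted p = 0.966), Cd68 by 0.22 (adjusted p = 0.776), Col1a1 by 0.74 (SE 0.248, adjusted p = 0.218) and Nphs1 by -0.16 (adjusted p = 0.772).

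In limma, 15 probe sets passed the interaction, 3 higher and 12 lower, and 2340 had an unadjusted p under 0.05. Median centring gave 6 higher and 3 lower. The count was 1, 1 or 0 without WKY control 1, 2 or 3. It was 1, 1 or 8 without SD control 2, 3 or 6, 76, 5, 7 or 27 without animal 2, 3, 4 or 5 of SD at 5 ml/kg, and 2, 2, 1 or 1 without animal 1, 2, 4 or 5 of WKY at 5 ml/kg. It was 107 with array weights, 3 with only the groups compared, 5 with quantile normalization, 6 with no filter, 6 with 1 probe set per gene and 7 with the replicate block. Without WKY control 1, 2 or 3, the adjusted p values were 0.161, 0.127 or 0.156 for Bcl6, 0.107, 0.127 or 0.156 for Nid1, 0.173, 0.127 or 0.0793 for Xbp1, 0.161, 0.125 or 0.0671 for Bbs7, 0.0928, 0.131 or 0.156 for Palm3 and 0.173, 0.104 or 0.156 for Znf750. These 6 genes also lost their calls without some SD animals or serum-treated WKY animals (adjusted p 0.0504 to 0.105) and under some processing alternatives (adjusted p 0.0509 to 0.135), Bcl6 under most.

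By list, the WKY response at 5 ml/kg exceeded the SD response for matrix genes (median difference 0.30, camera adjusted p = 0.000217). The WKY response was also larger for proliferation (0.23, camera adjusted p = 0.00014), macrophage (0.22, camera adjusted p = 0.0121) and injury genes (0.14, camera adjusted p = 0.0141). Oxidative phosphorylation genes differed by 0.08 (camera adjusted p = 0.0141). T-cell and NK-cell genes (-0.20) and interferon genes (-0.16) responded less in WKY (camera adjusted p = 0.0121 for each). T-cell genes such as Cd3e, Cd3d and Cd8a were below the filter. With an estimated correlation the T-cell and NK-cell list had an adjusted p of 0.264 and the other lists 0.568. In limma 0 members were called in each of these 7 lists. Adjusted over the list alone, 1 injury and 1 proliferation gene were higher, 3 interferon genes were lower and 1 higher, and the other lists had 0.

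With quantile normalization the adjusted p of the strain difference was 0.088 for injury, 0.088 for T-cell and NK-cell and 0.756 for oxidative phosphorylation genes. Without animal 1 or 6 of SD at 5 ml/kg it was 0.0589 or 0.177 for injury genes, and without animal 3 or 6 it was 0.0721 or 0.0781 for macrophage genes. For interferon genes it was 0.0881 or 0.0688 without animal 2 or 4 of that group and 0.071 without animal 3 of WKY at 5 ml/kg. For oxidative phosphorylation genes it was 0.0685 or 0.122 without animal 2 or 4 of SD at 5 ml/kg and 0.104 without WKY control 1.

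Across 11074 named genes, the log2 fold changes at 5 ml/kg in WKY and SD had a Pearson correlation of 0.804 and a Spearman correlation of 0.718; genes are not independent replicates. Of the calls at 5 ml/kg, 1899 probe sets were higher in both strains, against 519.9 for independent lists, and 1280 were lower in both, against 286. Calls in opposite directions numbered 19, against 774, and Bcl6 was among the genes that moved apart. For the 2247 genes called in both strains the correlation was 0.950 and 99.5% had the same sign, with a median absolute change of 0.47 in WKY and 0.39 in SD. Choosing called genes raises this agreement. With larger SEs in WKY (Havcr1 0.469, SD 0.371) calls need larger changes, so the medians do not compare response sizes.

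**Figure D5:**
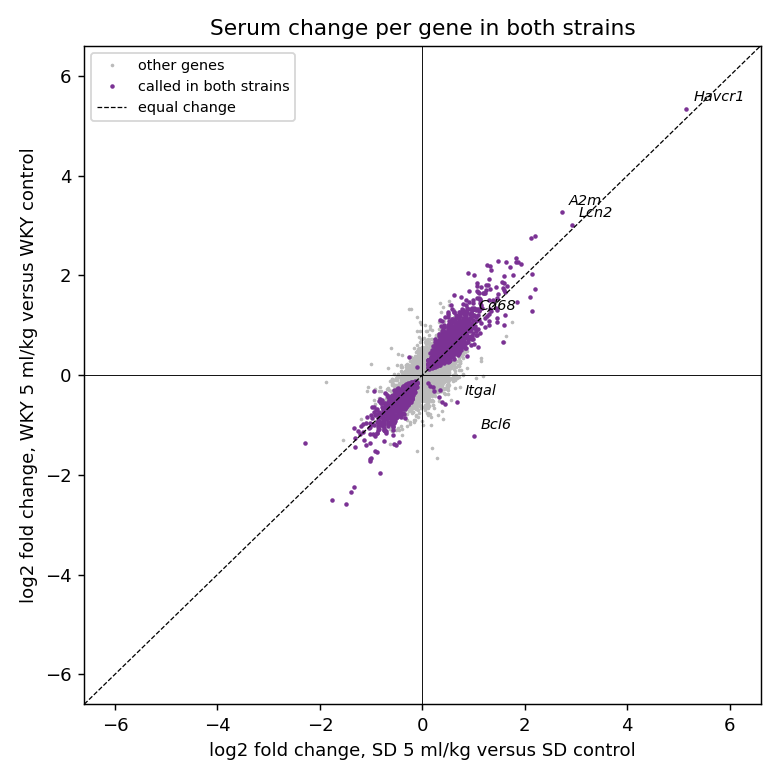
Each point is 1 of 11074 named genes, with its log2 fold change in SD at 5 ml/kg against SD controls on the horizontal axis and in WKY at 5 ml/kg against WKY controls on the vertical axis, in purple where called in both strains, and the dashed line marks equal change. Havcr1 lies at 5.15 in SD and 5.34 in WKY, and Bcl6 at 1.00 in SD and -1.22 in WKY.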

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

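The test of a kidney piece with less proximal tubule, the 3'/5' ratio covariates and the exchange of strain labels were chosen only after the results were seen.

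Bcl6, Havcr1 and Znf750 gave single animals far from the rest of their group. Bcl6 had a signal of 189 in SD 5 ml/kg animal 1 (others 523 to 709), 576 in WKY 1 ml/kg animal 2 (others 241 to 302) and 668 in WKY 2.5 ml/kg animal 3 (others 188 to 226). WKY 2.5 ml/kg animal 3 also stood apart for Havcr1, at 193 (others 528 to 594), and for Znf750, at 74.2 (others 43.0 to 48.7). Lcn2 was 44.8 in SD 1.5 ml/kg animal 6 (others 19.5 to 28.7), and Palm3 was 104 in SD control 1 (others 117 to 124). The 3'/5' ratio of Gapdh was 1.21 in SD control 4 (others 1.248 to 1.26) and 1.37 in SD 1.5 ml/kg animal 6 (lowest of the others 1.21), and that of Actb was 6.13 in SD 5 ml/kg animal 5 (others 3.75 to 4.51). These are 10 of 84 sets of values tested, and chance marks about 1 in 20.

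Between the strains, the response to 5 ml/kg differed in the interaction test for Nid1 (0.61), Xbp1 (-0.34), Bbs7 (-0.64), Palm3 (-0.76), Znf750 (-0.91), Itgal (-1.22) and Bcl6 (-2.22). By list it differed for injury (0.14), macrophage (0.22), T-cell and NK-cell (-0.20), matrix (0.30), interferon (-0.16), proliferation (0.23) and oxidative phosphorylation genes (0.0778), and all 7 lost this with an estimated correlation (adjusted p 0.264 to 0.568). The Itgal value is no measure of a response, since its WKY signals lay below the filter value of 16.9. Splits of treated and control arrays within each strain do not decide whether chance gave the 15 probe sets: 7 of 100 gave as many, the real one included, and the highest other gave 6795. Such a split moves the large serum effect between its arms, so counts that high decide nothing about chance. Exchanging strain labels within each treatment, with an equal serum response assumed, gave as many in 2 of 100 splits, the real one included, and 123 in the highest other. By that test chance would seldom give the 15, but the test was chosen after the results were seen. The count was also 1, 1 or 0 without WKY control 1, 2 or 3, so chance is not excluded.

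In WKY at 1 ml/kg, 75 of 95 called probe sets fell, Igfbp3 among them, in the group with the higher 3'/5' ratios. A piece of kidney with less proximal tubule is argued against: its list had a median of 0.0127 (SE of the median 0.0939, 24 members), where the lower probe sets had a median of -0.63. Its members went both ways (6 lower and 3 higher adjusted over the list alone, mean -0.12). Some rows lean toward less tubule: camera was downward with quantile normalization (median -0.0874, adjusted p = 0.000129) and without WKY control 1 (median -0.0010, adjusted p = 0.0486). A loss of proximal tubule, for part of the lower probe sets, stays open. RNA quality stays open and cannot be told apart from a dose effect, since the slope on the Gapdh ratio in the other groups gave a median share of 0.201 of the change (0.125 to 0.250 leaving out 1 array). With that ratio as a covariate, 1 of the 95 stayed past the threshold, the median absolute change went from 0.58 to 0.47 and the median SE from 0.127 to 0.136, and 95 of 95 kept their direction. An effect of the low dose itself stays open, untested.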

How the results depend on the processing

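The 3'/5' ratio covariates were chosen only after the results were seen. No named gene or list that was called changed direction under any alternative run, and counts, higher and lower together, stayed within 1.5 times their value except as follows; the cause was not tested unless stated. Requiring at least 1.5-fold, which can only lower a count, gave 47 probe sets in WKY at 1 ml/kg, 487 at 2.5 ml/kg, 1523 at 5 ml/kg, 30 in SD at 1.5 ml/kg, 1018 at 5 ml/kg, 1096 between the controls, 1672 and 840 between doses in WKY and SD, and 701 shared calls. Array weights gave 543, 4276 and 7887 in WKY at 1, 2.5 and 5 ml/kg, 4517 between the controls and 107 for the strain difference. With only the groups compared, where fewer arrays set the spread, there were 353 in WKY at 1 ml/kg, 0 in SD at 1.5 ml/kg (47 with all groups in limma, and 2235 at an unadjusted p under 0.05), 3 for the strain difference and 2553 between SD doses. With 1 probe set per gene, and so fewer tests, they were 10 in SD at 1.5 ml/kg, 1191 between the controls, 6 for the strain difference and 4508 between WKY doses. No filter gave 51 in WKY at 1 ml/kg, 26 in SD at 1.5 ml/kg and 6 for the strain difference. SD at 1.5 ml/kg also had 25 with the stricter filter, 29 with no offset, 82 with the higher offset and 31 with no trend. The strain difference had 5 with quantile normalization and 9 with median centring. Median centring also moved the balance of directions, to 9 higher and 75 lower in WKY at 1 ml/kg, 558 and 1411 at 2.5 ml/kg, 28 and 28 in SD at 1.5 ml/kg, 2136 and 4147 at 5 ml/kg, 1863 and 1362 between the controls, 6 and 3 for the strain difference and 1417 and 4883 between SD doses. The Actb ratio covariate gave 39 in WKY at 1 ml/kg and 18 in SD at 1.5 ml/kg, and the Gapdh ratio covariate 2 in WKY at 1 ml/kg.

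The replicate number as a block gave 50 in WKY at 1 ml/kg and 7 for the strain difference. The numbers do not pair animals: the mean residual correlation was -0.00068 in 96 pairs with the same number and 9.7e-05 in 456 with different numbers.

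With an estimated correlation, lists past the threshold numbered 0, 4 and 0 in WKY at 1, 2.5 and 5 ml/kg, 0 and 2 in SD at 1.5 and 5 ml/kg, 0 between the controls and 0 for the strain difference, against 1, 17, 18, 6, 20, 2 and 7 with the preset. Quantile normalization gave 2 in WKY at 1 ml/kg and 4 for the strain difference, and the mean over probe sets 1 between the controls.

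Leaving out 1 array in turn, the count ran from 0 to 84 in WKY at 1 ml/kg, 506 to 1987 at 2.5 ml/kg and 3446 to 5045 at 5 ml/kg. It ran from 10 to 53 in SD at 1.5 ml/kg, 4752 to 6743 at 5 ml/kg, 1639 to 2709 between the controls, 0 to 76 for the strain difference, 5713 to 6703 between WKY doses and 3850 to 6202 between SD doses. Shared calls ran from 2365 to 3588 and the correlation between strains from 0.763 to 0.828. Lists ran from 0 to 3, 15 to 19 and 18 to 19 in WKY at 1, 2.5 and 5 ml/kg, 4 to 9 and 20 to 21 in SD at 1.5 and 5 ml/kg, 2 to 3 between the controls and 6 to 9 for the strain difference. The lowest values in WKY counts against controls came without WKY control 3.

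Among named genes the call was lost in 59 cases with at least 1.5-fold, 182 leaving out 1 array, 15 with only the groups compared, 11 with median centring, 9 with no filter, 9 with the block and 7 with quantile normalization. Signal over background limits genes near the filter value of 16.9, where the offset of 5.35 shrinks fold changes, as for A2m in WKY at 5 ml/kg, from 2.47 to 3.99 over all alternatives, against 4.77 to 5.73 for Havcr1.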

Other observations

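The test of a clock difference between the strains alone was chosen only after the result was seen, and so were the clock gene lists.

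Circadian clock genes differed between the saline controls of the strains. Nr1d1, a repressor of the clock, was higher in WKY by 1.44 (adjusted p = 8.55e-06), with signals of 100.1 ± 13.1 (SD, n = 3) against 34.9 ± 12.8 (SD, n = 6) in SD. Its partners in phase Dbp, at 1.24 (adjusted p = 0.000997), Per3, at 1.09 (adjusted p = 0.00242), and Nr1d2, at 0.64 (adjusted p = 0.000597), were higher too. Genes of the opposite phase were lower: the activator Bmal1 at -0.87 (adjusted p = 0.000129), Cry1 at -0.72 (adjusted p = 0.000155) and Nfil3 at -1.16 (adjusted p = 0.000111). Of 13 members of both groups these 7 passed, and Hlf (-0.60, adjusted p = 0.0542), Per1 (-0.47, adjusted p = 0.383), Tef (adjusted p = 0.0614), Per2 (adjusted p = 0.621), Bhlhe41 (adjusted p = 0.0505) and Npas2 (adjusted p = 0.11) did not.

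The class II gene RT1-Bb varied from animal to animal within SD. They ran from 2.68 to 272 in SD controls (n = 6), from 4.19 to 375 at 1.5 ml/kg (n = 6) and from 4.66 to 566 at 5 ml/kg (n = 6). In WKY controls the signal was 495 ± 68.3 (SD, n = 3).

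Collection at another time of day is a candidate explanation for the clock pattern. Of 3 further clock genes tested (Usp2, Wee1 and Clock), 2 moved with their group between the controls and 0 did so with an unadjusted limma p under 0.05, too few genes to decide. In SD at 1.5 ml/kg 0 of the 3 moved with their group, and Usp2 went the other way (-0.37, SE 0.137). Clock genes also differed within SD, which a strain difference does not touch: from 1.5 to 5 ml/kg 6 of 13 members passed, with Dbp (-0.95), Hlf (-0.85), Nr1d1 (-0.70), Nr1d2 (-0.62) and Per3 (-0.68) lower and Nfil3 higher (0.83). Nr1d1 passed at 1.5 ml/kg against controls, and Hlf (-1.19), Per1 and Nr1d2 at 5 ml/kg. Of the further genes Usp2 (-0.60) passed there too, lower like the Dbp group. In WKY Hlf passed at 2.5 ml/kg (-0.82) and 5 ml/kg (-1.02), and so did Bmal1 (-0.51), Bhlhe41 (0.54) and, lower like Bmal1, Clock (-0.24) at 5 ml/kg. These last 3 calls were less stable. The adjusted p of Bmal1 was 0.12 without WKY control 1 and 0.0508 without animal 5 of the dose group, and that of Clock 0.0703 or 0.121 without WKY control 2 or 3 and 0.0587 without animal 2. Bhlhe41 had 0.198, 0.0615 or 0.0523 without WKY control 1, 2 or 3, 0.0688, 0.0522 or 0.0696 without animal 2, 4 or 5, 0.0539 with quantile normalization and 0.0553 with no filter. An effect of the serum on clock genes stays open, untested. For the 7 members that differed between the controls, a strain difference and another time of day cannot be told apart, since the labels give no time of day.

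Many strain differences of at least 2-fold may reflect a strain variant under the probes. Another probe set followed in 42 of 151 genes (27.8%), against 44 of 63 (69.8%) in WKY and 14 of 22 (63.6%) in SD for the serum response (Fisher's exact p = 1.76e-08 and 0.00138). The spread between animals, SD over WKY, had a median log2 ratio of 0.35 for 363 probe sets, against 0.25 in 10000 matched draws (permutation p = 0.001). Since 297 were lower in WKY, and the offset shrinks spread at low signals, variants segregating among outbred SD animals stay open. So does a true strain difference in expression, untested.

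Other splits of the same arrays, at the same group sizes, tested for chance. In WKY at 1, 2.5 and 5 ml/kg the counts were 95, 1648 and 5129, against 1, 397 and 1139 in the highest other of 56 splits. SD at 1.5 and 5 ml/kg gave 47 and 6169 against 6 and 4632, of 100 splits. Between doses, WKY gave 6846 against 2480 and SD 5393 against 3789, of 100, and the controls 2874 against 23, of 84. Only the real split gave as many, so chance would seldom do so. The low-dose counts were fragile: 0 in WKY without control 3 and 10 in SD without control 4.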
